A study of Rattus norvegicus with 12 samples.

How the data were processed

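The series measured RNA from rat Schwann cells of sciatic nerve on an Affymetrix rat array, with 12 arrays in 4 groups of 3: Control, NRG, IGF and NRG+IGF. Per the labels, total RNA was extracted with the RNeasy Plus kit and labelled with biotin. The deposited values are probe set intensity values from RMA, named in the submitters' processing notes without a version, and RMA corrects background, normalises arrays by quantiles and summarises the probes of a set. The table held 31099 probe sets with intensities from 6.15 to 22944.6, above what a log2 scale can reach, so they were read as linear and log2 was taken. No 2 array columns were identical (0 found), and 0 columns lacked a sample. The 12 array medians lay between 71.1 and 73.4, and the number of arrays limits the precision: 95% intervals reached a median of 0.26 in log2 to each side of the estimate (0.20 with the replicate number as a block), and 0.37 (0.28) for the interaction.

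Probe sets were joined to gene symbols through the array's annotation table. After 57 control probe sets were left out, 20826 probe sets named a single gene, 436 named several genes and were left out, and 9780 named none and were kept apart. Gene IDs of 20758 probe sets were found in a rat gene table of the GRCr8 assembly, used for names alone, and 0 symbols needed an update. For the 4525 genes with more than 1 probe set the brightest on average was used, which left 14217 genes. Positions on the genome are not given, since the array's own build was not at hand.

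Groups were taken from the labels. Linear models were fitted with limma 3.58.1 in R 4.3.3, with a coefficient per group, moderated statistics from eBayes and Benjamini-Hochberg adjustment over all genes within each comparison. The comparisons were each treatment against Control, NRG+IGF against NRG and against IGF, NRG against IGF, the interaction (NRG+IGF minus NRG minus IGF plus Control) and the moderated F test over the 4 groups. A gene was called at an adjusted p below 0.05. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

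The 33 gene lists held 1121 entries, of which 996 were measured. They covered ribosome biogenesis, cytosolic and mitochondrial ribosomal proteins, oxidative phosphorylation, mitochondrial import, chaperones and DNA maintenance, nuclear regulators of mitochondria, the tricarboxylic acid cycle, glycolysis, cholesterol and fatty acid synthesis, G1/S and E2F targets, DNA replication, mitosis, ERK feedback and targets, FOXO targets, amino acids, tRNA synthetases, translation, nucleotides, chaperones of the endoplasmic reticulum, proteasome, lysosome and autophagy, myelin, immature and repair Schwann cells, receptors and ligands of both factors, p53 targets, interferon response, extracellular matrix, and markers of fibroblasts, macrophages and leukocytes, endothelium, smooth muscle and pericytes, and perineurium. Lists with at least 5 measured genes were tested with camera of limma at its preset correlation of 0.01, adjusted over the lists of a comparison. Each list's genes were also adjusted over the list alone. Named genes were the 10 largest rises and falls against Control, or 5 in other comparisons, among called genes whose arrays did not overlap between the groups, up to 4 members per list and a set of genes named in advance. Genes that the probe table does not name were left out. The lists, tests, thresholds, naming rule and alternatives were set before the data were examined, except the alternatives, tests and lists that the closing section names as later.

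The labels number the replicates 1 to 3 in each group. After subtraction of group means, the 18 pairs of arrays with the same number correlated at 0.26 to 0.75 across genes (median 0.53), against a median of -0.32 and a highest value of 0.28 for different numbers, and each of the 12 arrays correlated best with 1 of its own number. The subtraction makes the values of a gene sum to 0 within a group. Same-number correlations above 0 therefore push those of different numbers below 0 by construction. Genes are not independent replicates in these correlations. The fit with the number as a block was kept as an alternative, as set beforehand, and its value is given beside a result where it changes the call. The labels do not say what the numbers stand for.

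The fit was tested on simulated data, drawn from each gene's mean and residual spread, in which 200 of 14217 genes were changed between NRG and Control. It recovered 30% of changes of 0.5 in log2, 92% of changes of 1 and 99.5% of changes of 2 (66%, 98.5% and 100% with the block), with 7, 7 and 12 false calls (7, 7 and 8 with the block). The data for the fit without the block held no difference between replicate numbers. Those for the block were drawn apart, with such a difference and the spread that the block leaves. How the fit without the block does on paired arrays was therefore not tested. A shift of 0.3 in the proteasome list was recovered by camera, with 0 other lists called. The simulated genes were drawn independently of each other, so this does not show how often camera calls lists of correlated genes falsely.

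The alternatives were the replicate block, genes above the median level alone, arrays centred on their medians, cyclic loess between arrays, a trended and robust variance prior, array quality weights, the mean of a gene's probe sets, a fit on the arrays compared alone, a change of at least 1 in log2, an adjusted p below 0.01, camera with an estimated correlation, fry in place of camera, and each array left out in turn. RNA quality was read from the 3' and 5' GAPDH control probe sets with an exact two-sided permutation test. Other splits of the arrays were counted, all 10 for each pair of groups, 100 draws for the 12 arrays and 100 draws within replicate numbers.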

Results

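Schwann cells, the glia that wrap the axons of peripheral nerves, were taken from rat sciatic nerve and profiled on 12 Affymetrix arrays. The cells had been held in the cell cycle with aphidicolin, an inhibitor of DNA polymerase, for 24 h in medium with 3% serum and then for another 24 h in medium without factors. They were collected 15 h after the addition of neuregulin (NRG), insulin-like growth factor (IGF), both, or neither (Control), with 3 arrays per group. The labels do not give the dose or isoform of either factor, or whether aphidicolin stayed in the medium during those 15 h. They also do not say whether the replicates came from separate cultures, so every p-value below measures only the spread between these arrays. Median intensities of the arrays lay between 71.1 and 73.4, and the number of arrays limits the precision. Of the variation among the 12 arrays, 41.1% lay between the groups and 38.8% between the replicate numbers, which pair the arrays. Values below are log2 fold changes ± SE with 3 arrays per group unless another unit is given. "Called" means an adjusted p below 0.05 over all 14217 genes, and the value with the replicate number as a block is given where it changes a call or moves a count by more than 1.5 times.

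**Figure D1:**
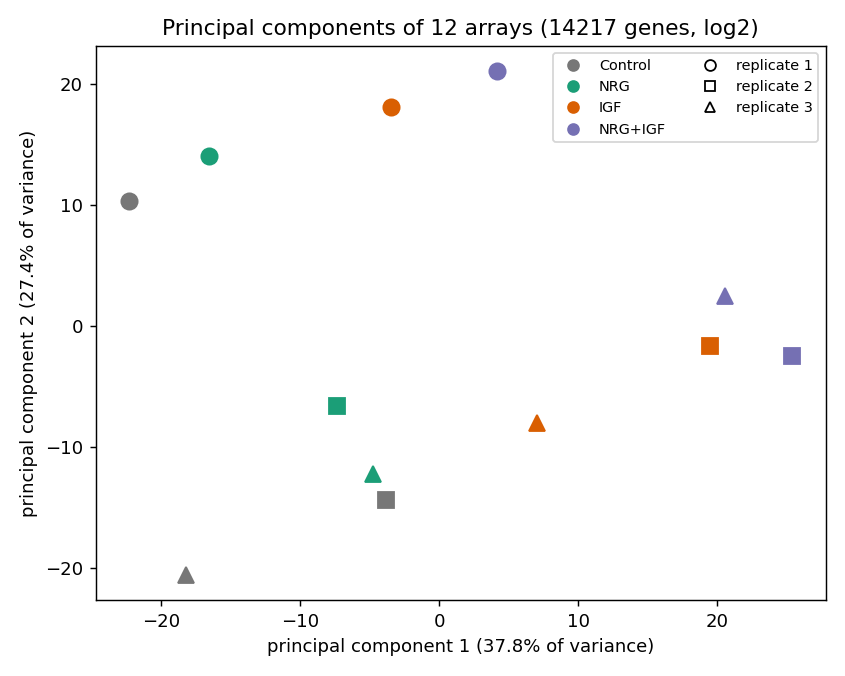
Principal components 1 (37.8% of the variance) and 2 (27.4%) of the 12 arrays, with a colour per group and a symbol per replicate number. The IGF and NRG+IGF arrays lie to the right of the Control and NRG arrays of the same replicate number.

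NRG alone gave small shifts, mostly upward, in the gene groups of cell division. All 42 genes for mitosis and all 35 for DNA replication lay above 0, with medians of 0.33 and 0.37, and 22 of the 25 G1/S and E2F target genes lay above 0, with a median of 0.33. Among them stood Ccne2, cyclin E2, which drives entry into S phase, at 0.85 ± 0.29 and Mcm5, a subunit of the replicative helicase, at 0.76 ± 0.24. Cdc25b, a phosphatase that activates the mitotic kinase, was at 0.50 ± 0.10. The 20 cholesterol biosynthesis genes had a median of 0.27 with all 20 above 0, and the genes of nucleotide synthesis and ribosome biogenesis had medians of 0.16 and 0.08. No single gene passed: limma called 0 genes (0 with the replicate number as a block), and 415 had an unadjusted p under 0.05 (1246 with the block), 278 higher and 137 lower than in Control. With no difference at all and unpaired arrays, a share of 0.05 of the 14217 genes would be expected there, which is above 415 and below 1246. The replicate numbers pair the arrays, so this share is no guide for the count without the block.

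As sets, 11 of the 33 gene lists passed limma's camera test for NRG against Control, and 0 did with an estimated correlation or with fry. The adjusted p was 1.16e-19 for mitosis, 2.92e-19 for DNA replication and 3.42e-10 for the G1/S list, and for each the adjusted p = 0.462 with an estimated correlation. It was 2.01e-08 for cholesterol biosynthesis (adjusted p = 0.499 with an estimated correlation), 4.05e-07 for nucleotide synthesis (0.462 in the same way) and 0.000228 for ribosome biogenesis (0.47). Glycolysis, the ERK feedback and target genes and the tRNA synthetases passed with medians of 0.12, 0.09 and 0.08, at adjusted p-values of 0.0166, 0.0239 and 0.0308 and adjusted p = 0.685, 0.47 and 0.859 with an estimated correlation. The median of the tRNA synthetases was -0.000936 without Control replicate 3. The FOXO target genes (median -0.07, adjusted p = 0.00773) and the p53 targets (median -0.06, adjusted p = 0.0433) were lower, with adjusted p = 0.462 and 0.537 with an estimated correlation. Adjusted over the list alone, Cdc25b was the 1 mitosis gene past the threshold (24 with the block), and 0 genes passed for DNA replication, G1/S and cholesterol (16, 8 and 4 with the block). In the same way Hbegf (0.41 ± 0.10) and Tgfa (-0.46 ± 0.11), both ligands of the EGF receptor, were the 2 ERK genes (3 higher and 1 lower with the block), named here after their values were seen. With the block, fatty acid synthesis (median 0.13, adjusted p = 0.0589 without the block and 0.00567 with it), amino acid synthesis and uptake (0.14, 0.167 and 0.0026) and extracellular matrix (0.08, 0.217 and 0.00917) passed as well.

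The shift with NRG alone was unequal between the replicate numbers. For DNA replication the median difference between NRG and Control was 0.26, 0.10 and 0.68 in numbers 1, 2 and 3, and for cholesterol biosynthesis it was 0.13, 0.09 and 0.63. Without NRG replicate 1 the number of lists that passed was 7, without Control replicate 2 it was 18, and another grouping of the same 6 arrays passed 21. That grouping did not part every replicate pair, and the other groupings that do passed 10 at most. Among receptors and adaptors of both pathways named beforehand, Irs2 (0.07 ± 0.20), Igf1r (0.01 ± 0.25), Erbb2 (0.16 ± 0.15) and Erbb3 (-0.15 ± 0.12) were not called.

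**Figure D2:**
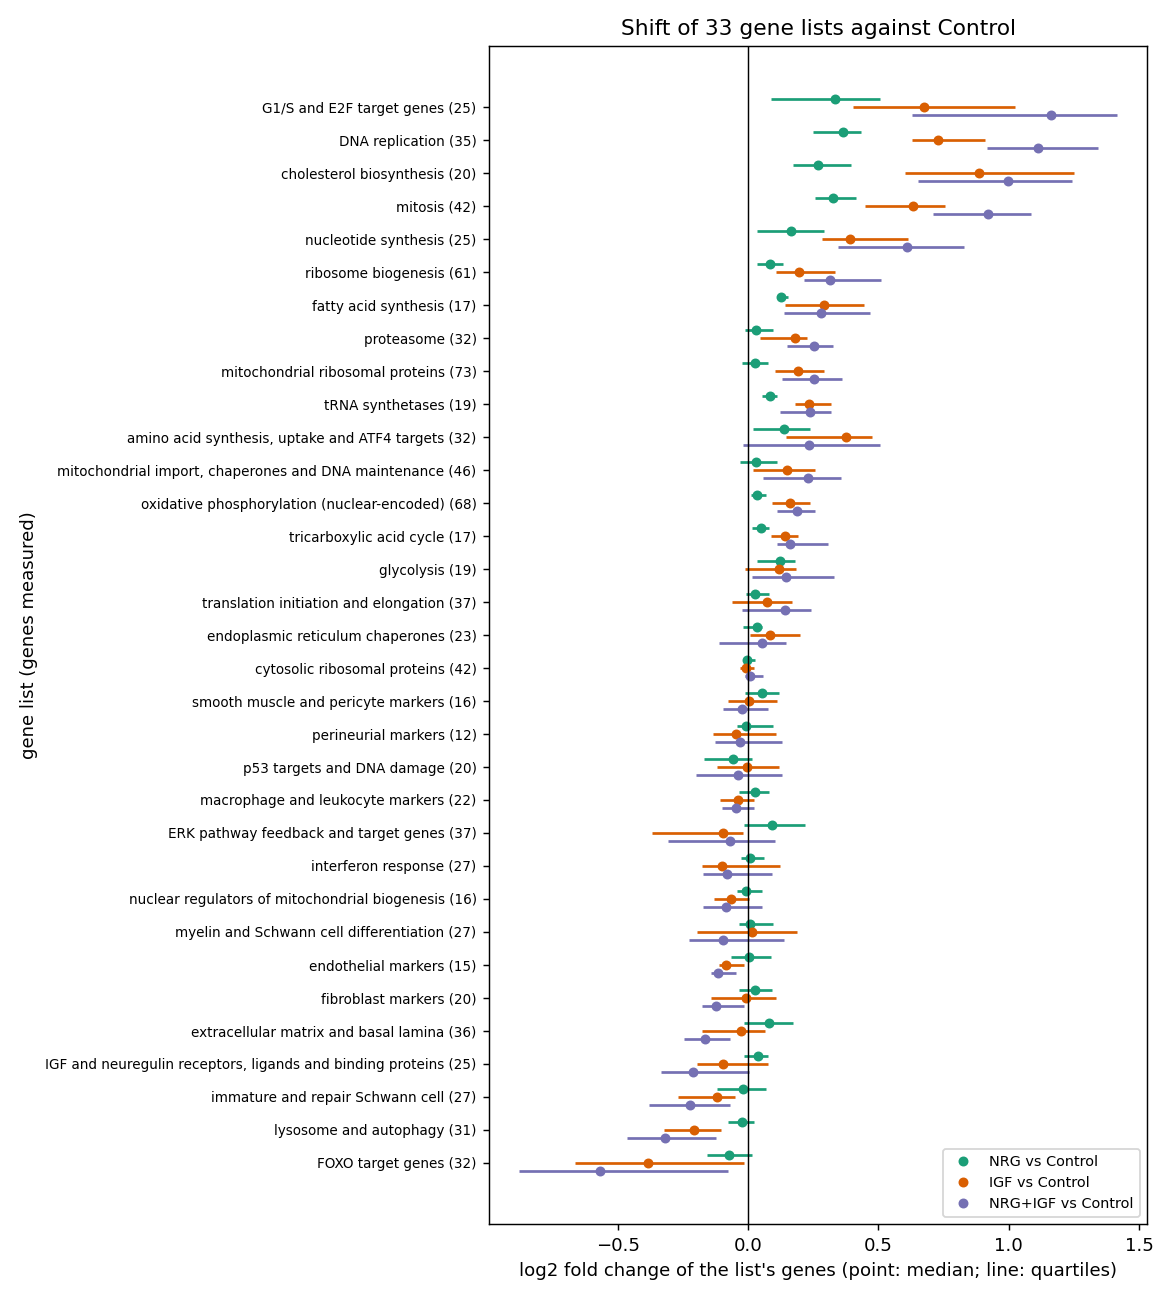
Shift of 33 gene lists with NRG, IGF and NRG+IGF against Control, as log2 fold change on the horizontal axis, with points for medians and lines for quartiles. The cell cycle and cholesterol lists lie highest, with NRG+IGF medians between 0.92 and 1.16, and the FOXO target genes lie lowest, at -0.57.

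IGF alone raised genes of the S phase machinery and of cholesterol synthesis. Ccne2 rose by 1.58 ± 0.29, from 9.56 ± 0.72 in Control to 11.14 ± 0.35 with IGF (log2 intensity, mean ± SD, n = 3). Ccne1, Mcm5 and Clspn, which carries the replication checkpoint signal, rose by 1.28 ± 0.22, 1.28 ± 0.24 and 1.35 ± 0.20. Idi1 and Fdps, which make the isoprenoid precursors of cholesterol, rose 2.99-fold and 2.36-fold, and Acat2, Insig1 and Hsd17b7 of the same list rose by 1.34 ± 0.21, 1.31 ± 0.27 and 1.30 ± 0.28. E2f7, a repressor of E2F targets, rose by 1.34 ± 0.20. A second, dimmer probe set of Ccne2 moved by 0.31 and was not called.

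By list, 14 of 35 DNA replication genes were called higher (32 adjusted over the list alone, 32 with the block), 8 of 42 mitosis genes (33 and 36), 10 of 25 G1/S and E2F targets (19 and 19) and 10 of 20 cholesterol genes (17 and 18). None of these lists held a gene called lower, and all 4 lay above Control in 3 of 3 replicate numbers. Their medians were 0.73, 0.63, 0.67 and 0.89, with camera's adjusted p at 1.3e-28, 7.01e-25, 2.45e-16 and 1.39e-21. These calls were lost with an estimated correlation (adjusted p = 0.127 for DNA replication, G1/S and cholesterol and 0.173 for mitosis with an estimated correlation). Nucleotide synthesis had 6 of 25 genes called higher (15 adjusted over the list alone, 15 higher and 1 lower with the block), among them Tk1, thymidine kinase (1.02 ± 0.16). Ribosome biogenesis had 3 of 61 (17, and 22 higher and 1 lower), with Fbl, the rRNA methyltransferase fibrillarin, at 0.66 ± 0.11. Their adjusted p-values were 5.72e-13 and 1.82e-11 (adjusted p = 0.127 for each with an estimated correlation).

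Some genes that insulin-like signalling holds down through FOXO transcription factors were called lower with IGF. Irs2, the adaptor that carries the signal from the insulin and IGF receptors, fell by 1.37 on the log2 scale (SE 0.20, adjusted p = 0.00818), from 8.63 ± 0.19 in Control to 7.26 ± 0.47 (log2 intensity, mean ± SD, n = 3). Of 32 FOXO target genes, 6 were called lower and 0 higher (16 lower and 1 higher adjusted over the list alone, 17 lower with the block). Among them were Klf15 (-0.92 ± 0.13), Cited2 (-0.83 ± 0.09) and Pik3ip1, an inhibitor of PI3K (-0.80 ± 0.17). The list's median was -0.38, below 0 in 3 of 3 replicate numbers, with camera's adjusted p = 1.96e-09 and adjusted p = 0.0569 with an estimated correlation. Lysosome and autophagy genes had a median of -0.21 (adjusted p = 1.26e-06, and adjusted p = 0.186 with an estimated correlation). The autophagy receptor Sqstm1 (-0.54 ± 0.08) and Gabarapl1 (-0.49 ± 0.09) were the 2 called of 31 (4 adjusted over the list alone, 9 with the block). The ERK feedback and target genes had a median of -0.10 (adjusted p = 0.000201, and adjusted p = 0.127 with an estimated correlation). Il6 (-0.91 ± 0.17) and Tgfa (-0.56 ± 0.11) were the 2 called of 37 (1 higher and 7 lower adjusted over the list alone, 1 and 12 with the block). Other genes that fell included Scn7a, a sodium channel (-1.25 ± 0.14), the transcription factor Bcl11a (-1.37 ± 0.24) and Nkd2, an inhibitor of Wnt signalling (-1.14 ± 0.10), together with Gda, Tcp11l2, Ypel3 and Avpr1a at -1.12 to -1.26. RT1-S3 also fell (-1.94 ± 0.16), but it belongs to the class I histocompatibility family, whose near-identical members an array may not separate. Cd200 fell by 1.13 on its brightest probe set and moved by 0.11 on a dimmer one.

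Mitochondrial genes shifted by less with IGF. The 68 nuclear-encoded genes of oxidative phosphorylation had a median of 0.16 with 65 above 0, and the 73 mitochondrial ribosomal proteins a median of 0.19 with 65 above 0. Yet 0 genes of either list were called by limma (11 and 20 with the block) or adjusted over the list alone (24 and 32 with the block). Camera gave adjusted p-values of 2.8e-09 and 3.66e-09 (adjusted p = 0.349 and 0.371 with an estimated correlation), and fry 0.108 and 0.164 (0.0089 and 0.0142 with the block). Mitochondrial import (median 0.15, adjusted p = 0.000139 and 0.348 with an estimated correlation), the tricarboxylic acid cycle (0.14, 0.00333 and 0.182) and the proteasome (0.18, 7.35e-06 and 0.348) passed higher in the same way. So did tRNA synthetases (0.23, 2.55e-06 and 0.247), fatty acid synthesis (0.29, 3.16e-06 and 0.247) and amino acid synthesis and uptake (0.37, 7.35e-06 and 0.349). The list of immature and repair Schwann cells passed lower (-0.12, 0.0208 and 0.271). Of these lists, amino acid synthesis had 1 gene called, Psat1 of serine synthesis (1.01 ± 0.20; 7 higher and 1 lower adjusted over the list alone, 16 and 2 with the block). The Schwann cell list had 1, Notch1 (0.53 ± 0.12), which rose against its list (1 higher adjusted over the list alone, 1 higher and 2 lower with the block). In fatty acid synthesis and the tricarboxylic acid cycle 0 were called by limma over all genes, against 5 and 2 adjusted over the list alone and 9 and 2 with the block.

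Over all genes limma called 271 between IGF and Control, 155 higher and 116 lower (1704 with the replicate number as a block, 993 higher and 711 lower), and 18 of 33 lists. The marker lists of other cells were not among them, with adjusted p from 0.257 to 0.9996 by fry with the block. Among single markers, only the fit with the block called Myl9 of smooth muscle (0.60) and Crabp2 of the perineurium (0.44) higher and Pdgfra of fibroblasts (-0.41) lower. The count of genes fell when some single arrays were left out, to 29 without IGF replicate 2, 57 without Control replicate 3, and 149, 168 and 175 without NRG replicate 3, Control replicate 1 and NRG replicate 2. Fewer arrays also lower the power, so these counts do not show that a single array carried the result. With the block, endoplasmic reticulum chaperones passed too (median 0.08, adjusted p = 0.0701 without it and 0.0105 with it).

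**Figure D3:**
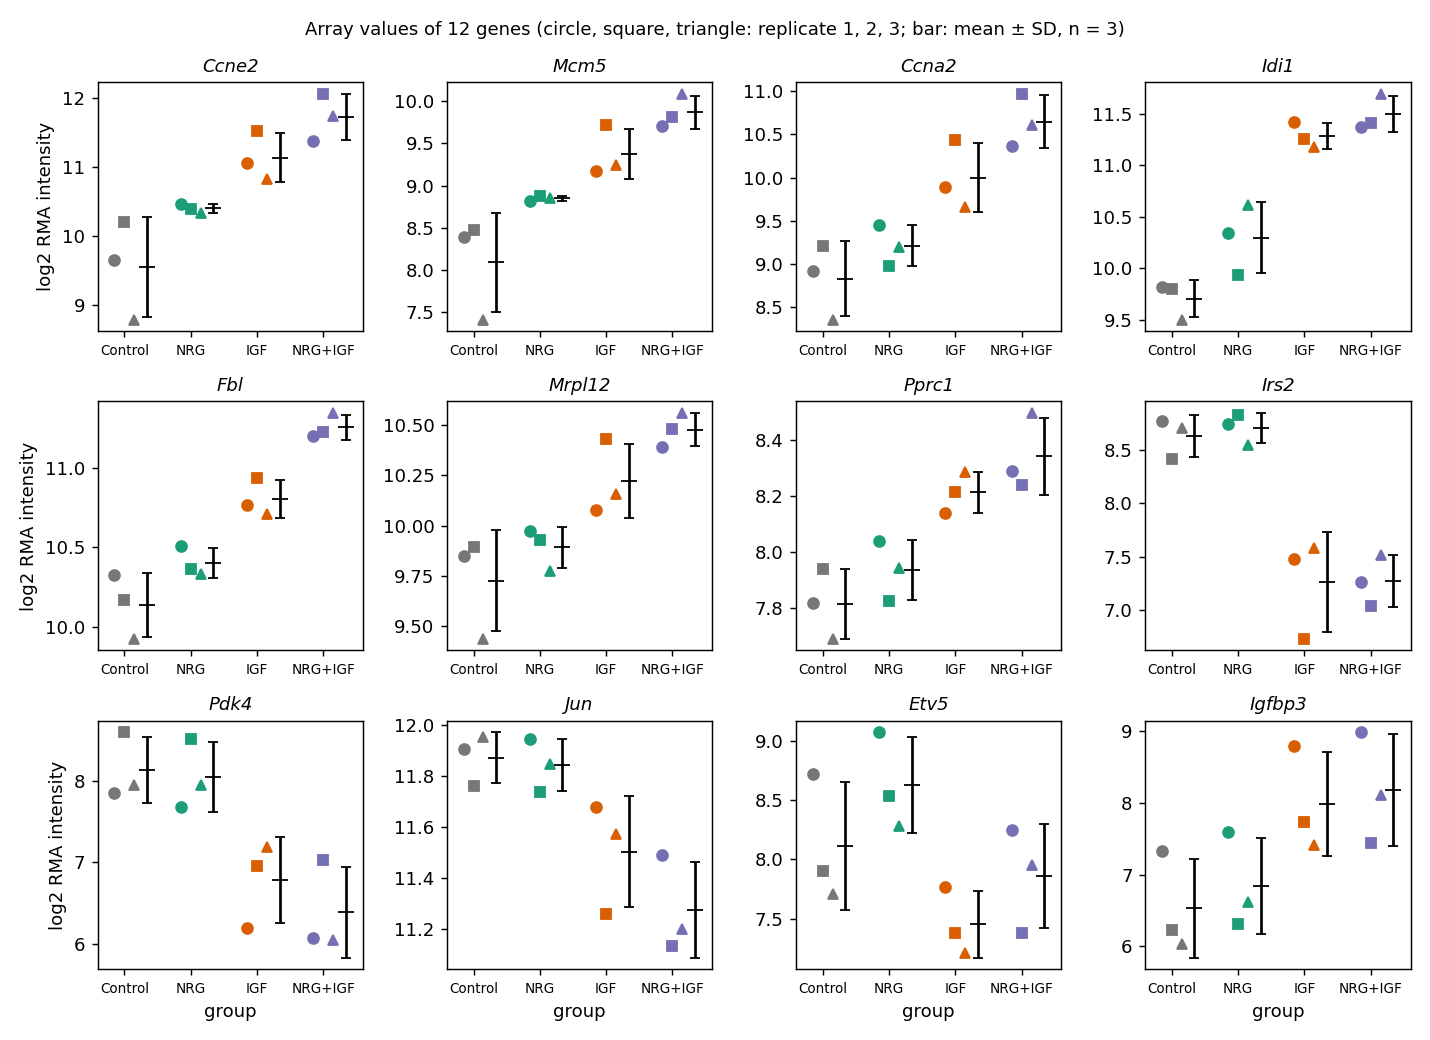
Log2 RMA intensity of 12 genes on each array by group, with circles, squares and triangles for replicates 1, 2 and 3 and bars for mean ± SD (n = 3). For Irs2 the 3 IGF and the 3 NRG+IGF arrays lie below the Control and NRG arrays, while Ccne2 means are 9.56, 10.40, 11.14 and 11.72 from Control to NRG+IGF.

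With both factors cell division genes rose, and most members of their lists were called. Ccne2 rose 4.5-fold (2.17 ± 0.29, adjusted p = 0.00109), from 9.56 ± 0.72 in Control to 11.72 ± 0.34 (log2 intensity, mean ± SD, n = 3). Clspn, E2f7, Ccne1 and Ccna2, cyclin A2, rose 3.86-fold, 3.74-fold, 3.58-fold and 3.52-fold. Of 35 DNA replication genes 31 were called higher (33 adjusted over the list alone), of 42 mitosis genes 33 (38) and of 25 G1/S and E2F targets 21 (22), and none was called lower. A second, dimmer probe set of Ccne2 moved by 0.32. Pole and Pola2, subunits of replicative DNA polymerases, rose by 1.68 ± 0.22 and 1.61 ± 0.22, the helicase subunit Mcm6 by 1.62 ± 0.22, Melk by 1.55 ± 0.19 and Pcna, the sliding clamp of replication, by 0.91 ± 0.17. The medians of these lists were 1.11, 0.92 and 1.16, with camera's adjusted p at 6.22e-32, 9.35e-30 and 2.43e-21 (adjusted p = 0.138, 0.138 and 0.0984 with an estimated correlation).

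Some genes of cholesterol synthesis, nucleotide synthesis and ribosome biogenesis were also called higher with both factors. Of 20 cholesterol genes 14 were called higher (17 adjusted over the list alone), led by Idi1 (1.79 ± 0.16) and Acat2 (1.49 ± 0.21), with a median of 0.997. Of 25 nucleotide synthesis genes 16 rose (20 higher and 1 lower adjusted over the list alone), with Tk1 at 1.39 ± 0.16 and Rrm1, the large subunit of ribonucleotide reductase, at 1.25 ± 0.16. Of 61 ribosome biogenesis genes 18 rose (34 adjusted over the list alone, 42 higher and 1 lower with the block), with Fbl at 1.11 ± 0.11, Nhp2 at 0.93 ± 0.16 and Nop56 at 0.82 ± 0.14. Of the 42 cytosolic ribosomal proteins limma called 0 (0 with the block; median 0.01). Camera's adjusted p was 2.73e-16 for cholesterol, 2.91e-16 for nucleotides, 1.62e-16 for ribosome biogenesis and 0.62 for cytosolic ribosomal proteins (adjusted p = 0.147, 0.0984 and 0.0792 for the first 3 with an estimated correlation).

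The median of the FOXO targets was lower with both factors, and some lysosome and autophagy genes were called lower. Of 32 FOXO target genes 16 were called lower and 0 higher (18 lower adjusted over the list alone). Among them were Pdk4, which shuts pyruvate out of the mitochondrion's oxidation (-1.75 ± 0.32), Irs2 (-1.36 ± 0.20), Pik3ip1 (-1.21 ± 0.17) and Cited2 (-1.13 ± 0.09). The median was -0.57, and camera's adjusted p was 4.22e-11. Of 31 lysosome and autophagy genes 7 fell (14 adjusted over the list alone, 19 with the block). The protease Ctsf was at -0.89 ± 0.17, Gabarapl1 at -0.68 ± 0.09, Sqstm1 at -0.66 ± 0.08 and Ulk1, the kinase that starts autophagy, at -0.60 ± 0.15. The list's median was -0.32 (adjusted p = 1.92e-08, and adjusted p = 0.138 with an estimated correlation). Of the calls of the 33 lists in all comparisons, that of the FOXO targets was the one that held with an estimated correlation, here (adjusted p = 0.0331) and for NRG+IGF against NRG (adjusted p = 0.0271). With the replicate number as a block and an estimated correlation together, 0 lists were called by camera in any comparison.

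Mitochondrial genes were higher by small amounts with both factors. Cyc1, cytochrome c1 of complex III (0.47 ± 0.10), Mdh2 of the tricarboxylic acid cycle (0.48 ± 0.09), Mrpl12 of the mitochondrial ribosome (0.75 ± 0.13), the RNA-binding protein Slirp (0.72 ± 0.17) and the import pore Tomm40 (0.59 ± 0.14) rose. Called higher were 2 of 68 oxidative phosphorylation genes (1 adjusted over the list alone, 23 with the block) and 6 of 73 mitochondrial ribosomal proteins (6, and 39 higher and 1 lower). So were 2 of 17 tricarboxylic acid cycle genes (2 and 7) and 10 of 46 import and DNA maintenance genes (17 and 23), and 1 import gene was called lower (2 and 2). The medians were 0.19, 0.25, 0.16 and 0.23, with camera's adjusted p at 2.31e-08, 2.49e-09, 0.000848 and 1.68e-06 and adjusted p = 0.386, 0.386, 0.138 and 0.252 with an estimated correlation. Of the 16 nuclear regulators of mitochondrial biogenesis, Pprc1, a coactivator of the PGC-1 family, was the 1 called (2 with the block; 0.52 ± 0.10, adjusted p = 0.00694), and the list's median was -0.08 (adjusted p = 0.62). Ppargc1a (-0.24 ± 0.12), Ppargc1b (-0.08 ± 0.15) and Nrf1 (-0.12 ± 0.10) were not called. Tfam, which packages mitochondrial DNA, was at 0.27 ± 0.10, with an adjusted p = 0.138 that was 0.0343 with the block and between 0.0343 and 0.565 over the 21 alternatives. Of these 21 the block was the 1 past the threshold, and the only 1 that takes the pairing of the arrays into account.

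Some genes of Schwann cell identity were called with both factors. Jun, a regulator of the repair state (-0.60 ± 0.13), and Erbb3, a receptor through which NRG acts (-0.52 ± 0.12), fell. So did Bdnf (-0.63 ± 0.15) and Mbp, myelin basic protein (-0.57 ± 0.16), while the myelin fatty acid carrier Pmp2 rose by 0.74 ± 0.19. The immature and repair list had 3 of 27 genes called lower (3 lower and 1 higher adjusted over the list alone, 6 and 2 with the block) and a median of -0.22 (adjusted p = 0.00564, and adjusted p = 0.21 with an estimated correlation). The 27 myelin genes had 1 called each way (2 higher and 1 lower adjusted over the list alone, 3 and 6 with the block) and a median of -0.10 (adjusted p = 0.504). Egr2, the master regulator of myelination, was at -0.70 ± 0.43, with an adjusted p = 0.369 that was 0.00127 with the block and lay between 0.00127 and 0.718 over the 21 alternatives. The block was again the 1 past the threshold, and the only 1 of the 21 that pairs the arrays. Among receptors, ligands and binding proteins, Igfbp3 (1.65 ± 0.47) rose and Irs2, Erbb3 and Nrg1 (-0.70 ± 0.18) fell (1 higher and 7 lower with the block), with a median of -0.21 over 25 genes (adjusted p = 0.00799, and adjusted p = 0.386 with an estimated correlation).

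Lists with smaller shifts also passed with both factors. The proteasome (median 0.25, adjusted p = 1.5e-07 and 0.292 with an estimated correlation), fatty acid synthesis (0.28, 0.000158 and 0.382) and tRNA synthetases (0.24, 0.000539 and 0.386) were higher. So were glycolysis (0.15, 0.0112 and 0.386), translation factors (0.14, 0.0136 and 0.386) and amino acid synthesis and uptake (0.23, 0.0163 and 0.606), while extracellular matrix (-0.17, 0.0185 and 0.641) was lower. In the amino acid list Psat1 (0.97 ± 0.20) and Cth (0.73 ± 0.17) rose, while the stress factor Atf3 (-1.24 ± 0.28) and the cystine transporter Slc7a11 (-0.87 ± 0.11) fell. The ERK list (median -0.07, adjusted p = 0.135), the p53 targets (-0.04, 0.377; Sesn1 and Xpc called lower, 2 higher and 3 lower with the block), endoplasmic reticulum chaperones (0.05, 0.509) and interferon response genes (-0.08, 0.503; Psmb9 called higher, 3 higher and 4 lower with the block) did not pass. By fry with the block the ERK list (adjusted p = 0.0449) and the p53 targets (0.0210) passed, while the chaperones (0.157) and the interferon genes (0.105) did not. Among genes outside the lists, Mlf1 (1.96 ± 0.36), the chemokine Ccl2 (1.91 ± 0.29) and the transcription factor Lhx2 (1.80 ± 0.18) rose. Scn7a (-1.88 ± 0.14), Tcp11l2 (-1.84 ± 0.22), Ypel3 (-1.59 ± 0.19), RT1-S3 (-1.59 ± 0.16), Crebrf (-1.47 ± 0.20), Bcl11a (-1.40 ± 0.24) and Klhl24 (-1.30 ± 0.13) fell. Ndrg2 fell by 1.63 on its brightest probe set and moved by 0.12 on a dimmer one.

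Markers of other cells that a nerve culture can hold did not pass camera as lists with both factors. The medians were -0.12 for fibroblasts (adjusted p = 0.108), -0.05 for macrophages and leukocytes (0.62), -0.12 for endothelium (0.135), -0.03 for perineurium (0.876) and -0.02 for smooth muscle and pericytes (0.815). By fry with the block the fibroblast list passed (adjusted p = 0.0398, and 0.0623 without the block), as it did against NRG (median -0.10, 0.0237 with the block), and its median was below Control in 3 of 3 replicate numbers. Of these markers Mfap5 (-0.98 ± 0.18) and Col3a1 (-0.40 ± 0.10) of fibroblasts were called lower (4 lower and 1 higher with the block). Coro1a, a leukocyte gene, stood at 0.67 (adjusted p = 0.0589 by limma, and 0.0126 with the block). Crabp2 (0.64 ± 0.18) of the perineurium and Myl9 (0.63 ± 0.16) of smooth muscle were called higher (2 higher and 1 lower, and 2 higher, with the block). These 2 lists had a median below 0 and a mean and camera direction above 0. The difference between the 3' and 5' probe sets of the GAPDH control, a sign of RNA quality, was -0.0959 ± 0.0611 in Control, -0.0169 ± 0.0800 with NRG, -0.0356 ± 0.0374 with IGF and -0.0386 ± 0.0247 with both (log2, mean ± SD, n = 3). Exact two-sided permutation p-values against Control were 0.2, 0.3 and 0.3, where the design allows no p below 0.1. Paired by replicate number, this difference was above that of the Control array in 9 of 9 pairs, by 0.0161 to 0.159, with an exact paired p = 0.25 for each treatment, the lowest that 3 pairs allow. For the beta-actin and hexokinase controls it was above in 2 and 7 of 9 pairs. In each case the 9 pairs share the same 3 Control arrays, so they are not independent of each other.

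Over all genes limma called 1379 between NRG+IGF and Control, 850 higher and 529 lower (3516 with the replicate number as a block, 1907 higher and 1609 lower), and 21 of 33 lists. The count of genes was 637 without Control replicate 3, 675 without NRG+IGF replicate 3 and 893 without NRG+IGF replicate 2.

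**Figure D4:**
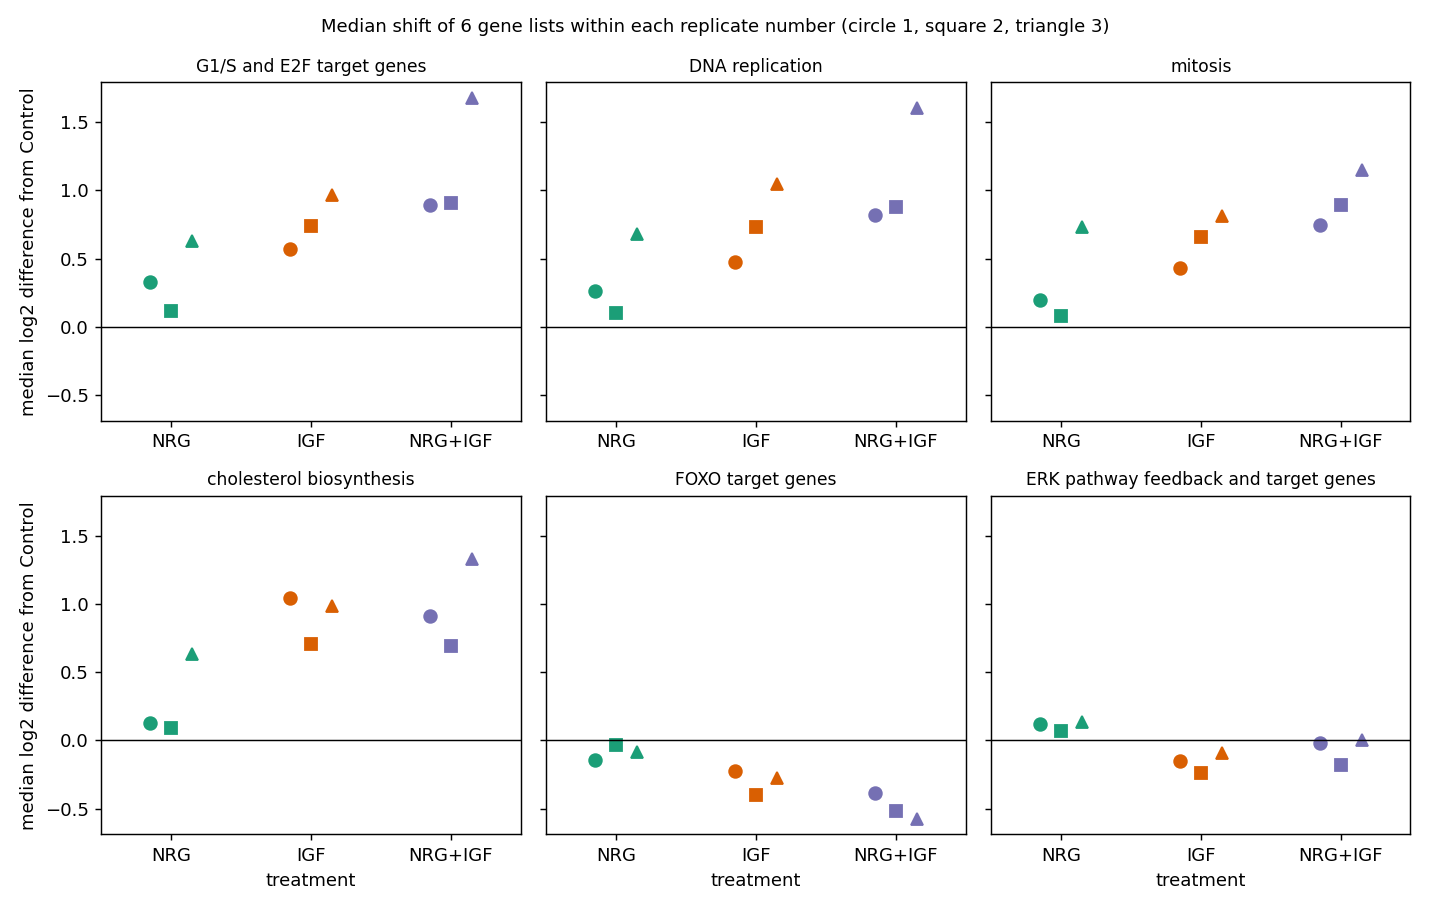
Median log2 difference from Control of 6 gene lists within replicate numbers 1 (circle), 2 (square) and 3 (triangle), by treatment. The DNA replication list lies above 0 in all 3 numbers with each treatment and highest in number 3, at 0.68 with NRG, 1.05 with IGF and 1.60 with both.

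Adding IGF to NRG raised Clspn (1.33 ± 0.20), Ccna2 (1.43 ± 0.24), Lhx2 (1.44 ± 0.18), Mlf1 (1.49 ± 0.36) and the kinase gene Rps6ka6 (1.43 ± 0.16). It lowered Pdk4 (-1.66 ± 0.32), Scn7a (-1.65 ± 0.14), Irs2 (-1.44 ± 0.20) and Tcp11l2 (-1.36 ± 0.22), besides RT1-S3 (-1.56 ± 0.16). Called higher were 19 of 35 DNA replication genes (32 adjusted over the list alone, 34 with the block), 11 of 42 mitosis genes (31 and 36) and 13 of 25 G1/S targets (21 and 22). So were 7 of 20 cholesterol genes (13 and 15) and 9 of 61 ribosome biogenesis genes (21 and 27), and called lower were 11 of 32 FOXO targets (18 and 19). Of the genes called for IGF against Control, 116 of 155 that were higher and 79 of 116 that were lower were called the same way here, on other arrays, and they made up 116 of the 265 higher and 79 of the 200 lower genes of this comparison. Independent lists would share 2.89 and 1.63, but these lists are not independent. Both comparisons use the same estimate of each gene's spread from all arrays, and the replicate numbers pair the arrays. Across all genes the IGF effects with and without NRG correlated at r = 0.80 (Spearman 0.69), though genes are not independent replicates.

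Camera passed 20 of 33 lists for NRG+IGF against NRG. The adjusted p was 1.12e-26 for DNA replication, 1.53e-22 for mitosis, 2.26e-19 for G1/S targets, 4.49e-15 for ribosome biogenesis, 1.78e-14 for nucleotides, 1.08e-13 for cholesterol and 8.86e-12 for the FOXO targets. The medians in the same order were 0.76, 0.56, 0.83, 0.23, 0.44, 0.70 and -0.44. With an estimated correlation the adjusted p was 0.159, 0.186, 0.13, 0.102, 0.13 and 0.186 for the first 6. The ERK list was lower (median -0.16, adjusted p = 0.000484 and adjusted p = 0.159 with an estimated correlation), with Jun the 1 gene called (-0.57 ± 0.13; 3 adjusted over the list alone, 12 with the block), as was extracellular matrix (-0.21, 0.000398 and 0.467). With the block the amino acid list passed (median 0.13, adjusted p = 0.0891 without it and 0.0262 with it). Limma called 465 genes, 265 higher and 200 lower (2563 with the replicate number as a block, 1344 higher and 1219 lower). That count was 52 without NRG+IGF replicate 3, 56, 125 and 114 without NRG replicates 2, 1 and 3, and 114 without NRG+IGF replicate 2.

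Adding NRG to IGF moved the medians of the cell cycle lists further up, by about as much as NRG alone did, with a smaller value for cholesterol genes. Across all genes the NRG effects with and without IGF correlated at r = 0.40 (Spearman 0.30). The medians of NRG+IGF against IGF were 0.35 for DNA replication (35 of 35 above 0), 0.32 for mitosis, 0.38 for G1/S targets, 0.13 for ribosome biogenesis and 0.23 for nucleotide synthesis, and 0.06 for cholesterol (adjusted p = 0.388). Mybl2, Ccna2 and Melk stood at 0.65 ± 0.14, 0.65 ± 0.24 and 0.62 ± 0.19, and the ERK targets Fosl1, a part of AP-1, and Ccnd1, cyclin D1, at 0.56 ± 0.23 and 0.45 ± 0.13. The FOXO targets were at -0.17 and lysosome genes at -0.10. No single gene passed: limma called 0 (0 with the replicate number as a block), and 604 had an unadjusted p under 0.05 (1674 with the block), 362 higher and 242 lower. The share of 0.05 of the 14217 genes expected with no difference lies above 604 and below 1674. As for NRG alone, it is no guide for the count without the block, which leaves the pairing out.

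Camera passed 17 lists for this comparison, but 0 passed with an estimated correlation, with fry or with fry and the block together. The adjusted p was 2.09e-17 for DNA replication (adjusted p = 0.372 with an estimated correlation), 3.1e-17 for mitosis (0.377) and 3.38e-16 for G1/S targets (0.206). It was 3.5e-10 for ribosome biogenesis and nucleotides (0.206 and 0.284), 2.69e-06 for FOXO targets (0.196), 0.000405 for lysosome genes (0.451) and 0.0255 for the ERK list (0.451, median 0.06). Adjusted over the list alone, 3 G1/S genes passed and 0 in each other list just named. With the block these were 12 for G1/S, 20 for DNA replication, 25 for mitosis, 4 each for ribosome biogenesis and nucleotides, 2 for the ERK list, 1 higher and 3 lower for FOXO targets and 0 for lysosome genes. The list of fibroblast markers was lower by a median of -0.07 (adjusted p = 0.00844, and adjusted p = 0.353 with an estimated correlation), as was extracellular matrix by -0.12 (0.00254 and 0.651). The number of lists was 9 without IGF replicate 1 and 11 without NRG+IGF replicate 2, and with the block the tricarboxylic acid cycle (0.0965 without and 0.0412 with it) and chaperones (0.189 and 0.0433) passed.

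Compared directly, the medians of the cholesterol and cell cycle lists were lower with NRG than with IGF, and those of the ERK and FOXO target lists were higher. With NRG, Idi1 and Fdps were lower than with IGF by -0.99 ± 0.16 and -0.99 ± 0.14, and Tgfb3 and Csgalnact1, an enzyme of chondroitin sulfate synthesis, by -0.85 ± 0.14 and -1.06 ± 0.17. Irs2 was higher with NRG (1.44 ± 0.20), as were Gda (1.26 ± 0.15), the sphingosine kinase Sphk1 (1.16 ± 0.12), the transcription factor Maff (1.14 ± 0.16) and RT1-S3 (1.92 ± 0.16), while Tmem86a was lower (-0.69 ± 0.11). Of 37 ERK genes 34 lay above 0, at a median of 0.27, and 0 were called by limma over all genes (7 adjusted over the list alone, 11 with the block), with Etv5, an ERK-induced transcription factor, at 1.18 ± 0.29. The adjusted p of Etv5 was 0.159, and 0.00111 with the block, with a range from 0.00111 to 0.548 over the 21 alternatives. Here too the block was the 1 past the threshold, and the only 1 of the 21 that pairs the arrays.

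By list, cholesterol stood at -0.63 with all 20 genes below 0 and 2 called (12 adjusted over the list alone, 15 with the block; adjusted p = 1.51e-16, and adjusted p = 0.32 with an estimated correlation). DNA replication stood at -0.41 and mitosis at -0.29 (adjusted p = 3.8e-15 and 2.5e-10, and adjusted p = 0.359 and 0.365 with an estimated correlation). With fry and the block together, DNA replication, mitosis and G1/S targets did not pass (adjusted p = 0.0698, 0.0825 and 0.0728), while cholesterol did (0.0269). Of these 3 cell cycle lists 0 genes were called (5, 3 and 1 lower and 1 G1/S gene higher with the block), and adjusted over the list alone 0 were lower (28, 17 and 17 with the block) and 1 G1/S gene was higher. The ERK list passed at 2.88e-09 and the FOXO targets, with a median of 0.24 and Irs2 and Cited2 (0.52 ± 0.09) called (11 higher and 1 lower adjusted over the list alone, 12 higher with the block), at 6.47e-08, each with adjusted p = 0.0512 with an estimated correlation and 0.00544 by fry. Camera passed 20 lists, and with the block also extracellular matrix (0.0605 without and 0.0169 with it). Limma called 24 genes, 18 higher with NRG and 6 lower (755 with the replicate number as a block, 441 higher and 314 lower). The count was 5, 6, 7, 8 and 12 without NRG replicate 2, NRG replicate 1, IGF replicate 2, IGF replicate 1 and NRG+IGF replicate 1, and 15 without Control replicate 2 or IGF replicate 3.

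The interaction asks whether the factors together differ from the sum of their separate log2 effects. On the intensity scale that sum is the product of the fold changes. With all arrays the medians of the cell cycle lists lay close to that sum, at of -0.01 for DNA replication (adjusted p = 0.928) and for mitosis (0.975) and of -0.0040 for G1/S targets (0.116), whose mean of 0.05 lay above 0. These values rested on single arrays: the DNA replication median was -0.13 without Control replicate 2 and 0.15 without Control replicate 3, with adjusted p = 0.00671 and 0.00372. Mitosis was at -0.15 without Control replicate 2 and 0.14 without NRG+IGF replicate 1 (adjusted p = 0.0135 and 0.0148), and the G1/S list at 0.21 without Control replicate 3 (0.000162). The cholesterol list fell short of it, with a median of -0.28 and all 20 genes below 0, led by Sqle (-0.40 ± 0.21) and Idi1 (-0.38 ± 0.23), neither of them called. The amino acid list (-0.25), extracellular matrix (-0.17), receptors and ligands (-0.11) and tRNA synthetases (-0.10) were below the sum and ribosome biogenesis (0.05) above it. No gene passed: limma called 0 (0 with the block), and 215 had an unadjusted p under 0.05 (688 with the block). The share of 0.05 of the 14217 genes expected with no difference lies above both numbers, but is no guide for the count without the block, which leaves the pairing out. Camera passed these 6 lists, at adjusted p-values of 0.000515 for the first 3 and of 0.0397, 0.0397 and 0.0472 (adjusted p = 0.925 for each with an estimated correlation). The number was 10 with the replicate number as a block, which added import and DNA maintenance, fatty acid synthesis, myelin and fibroblast lists. It was 0 without NRG replicate 1 or IGF replicate 1, 2 without NRG+IGF replicate 2, 13 without NRG replicate 2, 15 without Control replicate 3 or NRG+IGF replicate 1 and 19 without IGF replicate 2. Over the 4 groups together, the moderated F test of limma called 750 genes (2842 with the replicate number as a block), and 295, 382, 423 and 468 without NRG+IGF replicate 3, Control replicate 3, NRG+IGF replicate 2 and NRG replicate 2.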

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

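The test of the interaction, the estimated correlation, the arrays left out in turn and the draws of the arrays were set beforehand. The choice to hold the estimated correlation and the arrays left out against an explanation came after the result was seen. The tests of compression, of replicate number 3 and of fibroblasts were chosen after it.

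For 6 gene lists the interaction of the factors passed camera at its preset correlation, but 0 lists passed with the correlation estimated from the data (adjusted p = 0.925 for each). Of 100 draws of the arrays 84 gave as many, but these draws can move the effect of IGF into the contrast, so that share does not measure chance alone. The median interaction was -0.280 for cholesterol biosynthesis, -0.248 for amino acid synthesis, uptake and ATF4 targets, -0.167 for extracellular matrix, -0.113 for receptors, ligands and binding proteins of both factors, -0.101 for tRNA synthetases and 0.0456 for ribosome biogenesis. Compression of bright signals by the array was argued against for cholesterol, where the 10 dimmer genes had a median interaction of -0.307 and the 10 brighter genes -0.202, although compression would shrink the brighter ones more. Correlation of genes within a list may account for the calls, by the value above, and a single array may also carry them, since 0 lists passed without NRG replicate 1, and 0 without IGF replicate 1. A response of cholesterol genes below the sum of the log2 effects is a biological alternative that stays open, as a hypothesis that these arrays do not settle. That sum is the product of the fold changes, and additivity of the intensities was not tested.

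Probe sets with no gene listed held differences too, in data that the gene comparisons do not use. Of 9780 such probe sets limma called 61 between IGF and Control (22 higher and 39 lower), 334 between NRG+IGF and Control (175 and 159), 87 between NRG+IGF and NRG (46 and 41) and 12 between NRG and IGF (12 and 0).

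The 3 cell cycle lists were higher with NRG alone, and more so in replicate number 3 than in numbers 1 and 2. Number 3 as the sole carrier cannot be told apart from a shift in all numbers: with numbers 1 and 2 alone all 3 lists passed at the preset correlation, at medians of 0.19 for G1/S and E2F targets, 0.17 for DNA replication and 0.15 for mitosis and adjusted p-values of 0.000159, 5.74e-06 and 0.000233, but 0 passed with an estimated correlation (adjusted p = 0.886 for each). RNA quality cannot be told apart either, with 1 pair of arrays per number: the 3' minus 5' signal of NRG minus Control was 0.0390 in number 3 and 0.0393 and 0.159 in numbers 1 and 2 for GAPDH, but lowest in number 3 for beta-actin (-0.0733, against -0.0533 and 0.317) and hexokinase (-0.0705, against 0.0227 and 0.388). A low Control array of number 3 cannot be told apart from a stronger response there: all 3 lists also had their highest NRG+IGF minus IGF median in number 3, with 1 array per group and number. The labels name no difference between the numbers, so no biological explanation was tested.

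The fibroblast markers were lower with NRG+IGF than with IGF, at a median of -0.07 and an adjusted p = 0.353 with an estimated correlation. Fewer fibroblasts in those cultures cannot be told apart from lower expression of these genes. Of the 4 abundant markers 0 lay more than 3 standard errors above their median of -0.28: Col1a1 stood at -0.23, Col1a2 at -0.16, Col3a1 at -0.32 and Pcolce at -0.34. Of all 20 markers 4 lay that far above it (Dcn, Pdgfra, Thy1 and Dpt, at 0.03, 0.16, 0.12 and 0.17), but their mean log2 intensities of 3.75, 5.08, 5.45 and 4.64 were below the array medians, so that they exclude nothing. Less abundant markers above the array medians did not fall alike. Gsn stood at 0.0099, Fbln1 at 0.0017, Pi16 at -0.06 and Ogn at -0.13, from 1.80 to 2.95 standard errors above that median. Mfap5 stood at -0.59, below it by 1.91 standard errors. Lower collagen expression within the Schwann cells themselves was not tested and stays open.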

How the results depend on the processing

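Chosen after the data were seen were the fits on every probe set and on numbers 1 and 2 alone (with camera's correlation preset or estimated), and the block together with an estimated correlation or with fry. The cause was not tested for the changes below except where the construction shows them. Of 178 calls of named genes, 178 held with the replicate block and with cyclic loess, 177 with the trended robust prior, 174 with arrays centred on their medians, 170 with array weights and 161 with the mean of probe sets, and all 141 of those above the median level held there. With fewer arrays, 122 held with only the arrays compared and 24 with only numbers 1 and 2. At 2-fold or more 94 held and at an adjusted p below 0.01 85 did. With 1 array left out 117 held without NRG+IGF replicate 3, 127 without Control replicate 3, 129 without NRG replicate 2 or NRG+IGF replicate 2, and up to 160 without the others. None of these 178 calls reversed (0 reversed), and genes outside them were not followed in this way. Of 113 list calls, 113 held with the block, 112 with centring, 107 with the mean of probe sets, 106 with cyclic loess, 103 with genes above the median level, 97 with numbers 1 and 2, 72 with fry and the block, 38 with fry and 2 with an estimated correlation. The replicate numbers pair the arrays, and the block, which removes 38.8% of the variation, raised the genes called to 1704 for IGF against Control, 3516 for NRG+IGF against Control, 2563 for NRG+IGF against NRG, 755 for NRG against IGF and 2842 for the F test, and the interaction lists to 10. Genes above the median level gave 12 interaction lists, and array weights 998 genes for NRG+IGF against NRG.

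Stricter thresholds lowered counts by construction, while fewer arrays moved counts both ways, as the ranges below show. With only the arrays compared, 24 genes were called for IGF against Control, 831 for NRG+IGF against Control and 5 for NRG against IGF. At 2-fold or more the counts were 40 for IGF and 209 for NRG+IGF against Control, 47 for NRG+IGF against NRG, 11 for NRG against IGF and 193 for the F test, and at an adjusted p below 0.01 they were 31, 552, 62, 5 and 210. Every non-control probe set gave 38 for NRG against IGF. Numbers 1 and 2 alone gave 1 for IGF and 84 for NRG+IGF against Control, 0 for NRG+IGF against NRG, 1 for NRG against IGF and 4 for the F test, and 6 lists for NRG against Control.

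Lists depended most on the correlation assumed within them. With the correlation estimated from the data, 0 lists passed for NRG and 0 for IGF against Control, 1 for NRG+IGF against Control, 1 for NRG+IGF against NRG, and 0 for NRG+IGF against IGF, for NRG against IGF and for the interaction. With fry, which asks another question, they were 0 for NRG, 10 for IGF and 12 for NRG+IGF against Control, 0 for NRG+IGF against IGF, 2 for NRG against IGF and 0 for the interaction. The block with an estimated correlation, and numbers 1 and 2 alone with an estimated correlation, each gave 0 in all 7 comparisons, and the block with fry 0 for NRG against Control, for NRG+IGF against IGF and for the interaction.

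With each array left out in turn, genes called ranged from 29 to 284 for IGF and 637 to 1384 for NRG+IGF against Control, 52 to 514 for NRG+IGF against NRG, 5 to 24 for NRG against IGF and 295 to 721 for the F test. They stayed at 0 for NRG against Control, NRG+IGF against IGF and the interaction. Lists ranged from 7 to 18 for NRG, 18 to 21 for IGF and 18 to 22 for NRG+IGF against Control, 20 to 22 for NRG+IGF against NRG, 9 to 21 for NRG+IGF against IGF, 16 to 21 for NRG against IGF and 0 to 19 for the interaction. In 6 results, over 5 lists, the direction that camera gives a list turned where it was called with or without the array. The ranges that follow are of medians, which need not turn with it. For DNA replication and mitosis in the interaction they were already below 0 with all arrays (-0.0098 and -0.0074). The interaction ran from -0.13 without Control replicate 2 to 0.15 for DNA replication, from -0.15 without Control replicate 2 to 0.14 for mitosis, and from -0.051 to 0.039 without Control replicate 3 for oxidative phosphorylation. NRG against Control ran from -0.050 without Control replicate 3 to 0.085 for mitochondrial ribosomal proteins and from -0.000936 without Control replicate 3 to 0.13 for tRNA synthetases. NRG+IGF against IGF ran from -0.015 without NRG+IGF replicate 2 to 0.10 for mitochondrial ribosomal proteins. Of lists called with all arrays, 3 other medians crossed 0 as their calls were lost: extracellular matrix (0.0090 without NRG+IGF replicate 2) and the amino acid list (0.03 without NRG+IGF replicate 3) for NRG+IGF against IGF, and receptors and ligands for the interaction (0.02 without NRG+IGF replicate 2). Signal near background was not modelled, since the deposited values carry no detection calls.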

Other observations

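The 6 gene lists in the first paragraphs and their tests were chosen after the results were seen, as were the draws within replicate numbers at the end, and the other counts over splits of the arrays were set beforehand. The p-values of these 6 lists come from the arrays on which the lists were chosen and are adjusted over the 6 alone. They describe the lists and are not independent support for a shift. The block and an estimated correlation together were not applied to these lists.

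Genes that carry RNA out of the nucleus and process it were among those called higher with both factors. Of 29 nuclear pore genes 17 rose against Control and 0 fell (21 with the replicate number as a block), at a median of 0.44, with Nup43 at 1.27 ± 0.20 and Nup85 at 1.20 ± 0.20. Of 40 spliceosome and splicing genes 19 rose (25 with the block), at a median of 0.38, with Snrpa of the U1 particle at 1.30 ± 0.15 and the splicing factor Srsf2 at 1.18 ± 0.09. Camera's adjusted p over the 6 lists was 2.00e-13 and 5.79e-13, and for each the adjusted p = 0.0203 with an estimated correlation. With IGF alone the medians were 0.29 and 0.26, with 4 and 5 genes called (13 and 20 with the block) and adjusted p = 0.0240 for each with an estimated correlation. Fanconi anaemia and homologous recombination genes, which repair broken replication forks, had a median of 0.56 with both factors (adjusted p = 1.59e-08, and adjusted p = 0.181 with an estimated correlation). Of its 23 genes 10 rose and 1 fell (16 and 1 with the block), with the nuclease Exo1 at 1.47 ± 0.20, Brca1 at 1.39 ± 0.27 and Fancd2 at 1.32 ± 0.25.

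Of 10 cholesterol efflux and LXR target genes 3 fell with both factors (4 lower and 1 higher with the block), among them the sterol exporter Abca1 (-1.09 ± 0.24) and Mylip (-1.10 ± 0.18), while Lpcat3 stood at 0.32 ± 0.11. The list's median was -0.18 (adjusted p = 0.0384, adjusted p = 0.245 with an estimated correlation and 0.00249 by fry with the block). Chemokines and cytokines went both ways, with Ccl2 at 1.91 ± 0.29, Cxcl12 at 1.02 ± 0.19, Ccl7 at 0.57 ± 0.14 and Il6 at -0.995 ± 0.17. The list of 26 did not pass for both factors against Control (median -0.06, adjusted p = 0.717, and 0.142 by fry with the block). It was higher with NRG than with IGF (median 0.12, adjusted p = 0.00295, adjusted p = 0.0464 with an estimated correlation and 0.00265 by fry with the block), and with both factors than with IGF (0.03, 0.0215, 0.0765 and 0.0635). By fry with the block it was also lower with IGF than in Control (median -0.09, adjusted p = 0.00377, and 0.0682 by camera) and with both factors than with NRG (-0.09, 0.0206 and 0.304). Circadian clock genes did not pass camera as a list with both factors (median -0.12, adjusted p = 0.160) but passed fry with the block (0.0338, and 0.0206 against NRG), and Nr1d2 (-0.45 ± 0.10) and Bhlhe41 (-0.60 ± 0.16) fell.

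For each pair of groups the 6 arrays can be split in 10 ways, too few for a share under 0.05. The genes called in the real split and the highest of the others were 271 and 0 for IGF against Control, 1379 and 0 for NRG+IGF against Control, 465 and 0 for NRG+IGF against NRG and 24 and 0 for NRG against IGF, so that 1 split of 10 was as large in each. For NRG against Control and for NRG+IGF against IGF they were 0 and 0, so that all 10 splits were as large by construction and say nothing about chance. For lists passed by camera the real value and the highest other were 11 and 21 for NRG against Control (4 splits as large, the real 1 included), 18 and 24 for IGF against Control (3) and 21 and 20 for NRG+IGF against Control (1). They were 20 and 16 for NRG+IGF against NRG (1), 17 and 20 for NRG+IGF against IGF (3) and 20 and 20 for NRG against IGF (2). The replicate numbers pair the arrays, and 4 of the splits part all 3 pairs, as the real one does. Among those the highest others were 10, 18, 18, 14, 11 and 13 lists in the same order, and the splits that keep a pair together hold the difference between numbers as well.

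Over 100 draws of the 12 arrays into 4 groups, the F test called 750 genes in the real grouping and 0 at most in the others. With 1 of 100 as large, the real grouping included, chance was unlikely under these draws but is not excluded. For the 6 lists of the interaction, 84 of 100 draws were as large, with 25 in the highest other, so chance is not excluded. The draws can place the arrays with IGF unevenly on the contrast, at most 5 on one side, so the effect of IGF can enter it. The share therefore does not measure chance alone. With 0 interaction genes in the real grouping, 100 of 100 draws were as large by construction, so that count says nothing about chance. The highest others, at 464 and 133 genes, point to a structure of the samples, whose source these draws do not settle. The draw with 464 genes had 5 of the 6 arrays with IGF on one side of the contrast, but 6 of the 7 draws with that many called 0.

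These draws ignore that the replicate numbers pair the arrays. Over 100 draws within the numbers, the F test with the replicate number as a block called 2842 genes in the real grouping and 1733 in the highest other. Chance was unlikely under these draws but is not excluded (1 of 100 as large, the real grouping included). Without the block it called 750 and at most 259 (1 of 100). For the interaction lists with the block chance could not be excluded, at 10 in the real grouping and 22 in the highest other (60 of 100 as large). Here too the draws can move the effect of IGF into the contrast, so the share does not measure chance alone.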
